A study of Phaeodactylum tricornutum with 12 samples.

How the data were processed

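The series holds 12 mRNA libraries of Phaeodactylum tricornutum in 4 groups of 3, with 2 strains and 2 nitrogen levels. Per the labels' protocols, mRNA was taken with oligo-dT and sequenced on an Illumina platform after 48 h with 0.88 mM nitrate or with no nitrogen source. The deposited count table gives unnormalised read counts per gene model for each library, per the file headers, and its columns are whole numbers with different totals. The aligner, the counting program, the genome build and the use of strand in counting are not given in the sources used here, so reads of a gene, of an antisense transcript and of an introduced construct with the same sequence cannot be told apart. The submitters' processing notes name DESeq 1.10.1 without saying how it was set. The 4 tables that the authors deposited beside the counts give, per the file headers, the mean normalised signal of each group, made as counts divided by size factors and averaged over the replicates. The same deposited tables give the log2 fold change between those means and, per the file headers, a p-value and an adjusted p-value for each gene. The mean signal in the first group column of each deposited table correlated across genes with the CPM of the group that the table's header or name gives first at r = 0.992 to 0.994, against 0.831 to 0.971 with the table's other group. In the NR nitrogen table the headers of the group means name NR12 where that of the fold change names NR21, and both were taken as the same strain.

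The table lists 10402 gene models, of which 10181 were matched by number to a reference gene table (assembly ASM15095v2, used for names only) and 221 were not. The reference gives no products and gives symbols for 608 of the models. A further 2 symbols carried by more than 1 model of the same number were left out as ambiguous, and 131 models had no count in any library. Where the text says what a gene is known to do, it reads the symbol in its usual sense. The targeted gene was taken as Phatr2_54983, the number written down for nitrate reductase before the data were examined, since the reference names no function for it.

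Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, which left 9717, libraries were scaled by TMM, and the quasi-likelihood test was run on the means of the 4 groups in 1 fit over all 12 libraries. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene is called changed at an adjusted p under 0.05. Values are CPM after TMM scaling as mean ± SD of 3 libraries, except for strain-marking genes, which are CPM of the library total. Log2 fold changes come from the edgeR fit, each with a standard error taken from its quasi-likelihood F value. The comparisons were without nitrogen against with nitrate in each strain, NR against WT at each nitrogen level, and the difference between the strains' nitrogen responses (the interaction). The groups, the comparisons, the tests, the alternatives, 25 gene lists and the rule for naming genes were set before the data were examined.

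Of those 25 lists, which match words in names and products, 6 had the 3 tested members needed for a test, because the reference has symbols only. A second set of 27 lists was written from the reference's symbols after the files had been opened and before any listed gene was tested, and 1 of these was replaced by the fixed list that held nearly the same genes, which left 32 lists. The lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Camera adjusted p-values below are per comparison and with the preset correlation unless stated. Adjustment over all lists and comparisons together was also planned, and calls lost by it are given below for the nitrogen comparisons. The words of the fixed photosystem list also matched PSAT, by its usual reading an enzyme of serine synthesis, and those of the fixed list for division matched only MCM and PCNA genes.

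Genes are named by this rule: the targeted gene, the 2 genes per comparison that rose most and the 2 that fell most (called, with a mean of at least 5 CPM in the higher group and, between groups, no overlap of libraries), and for a described list up to 4 called members with the largest change or, where none was called, up to 2 with the smallest p as values only. Because no products are given, the genes that rose or fell most are named by identifier. A gene outside the rule is said to have been chosen after its values were seen.

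The alternatives were DESeq2 size factors, library size alone, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, each library left out in turn, the replicate number as a block, only the groups compared and at least a 2-fold change. A fit without the libraries labelled WT_minusN replicate 1 and NR_minusN replicate 2, and leave-one-out values for the correlations across genes, were added after seeing the data. The alternatives were first run for named genes of called lists and extended to all named genes after a first text was written. Explanations were tested with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 drew the figures. Tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the edgeR step recovered 54 and 98 of them for the WT nitrogen comparison (9668 genes), 48 and 96 for the NR nitrogen comparison (9665 genes), 53 and 99 for the strains with nitrate (9659 genes), 53 and 94 for the strains without nitrogen (9663 genes), and 11 and 72 for the interaction (9656 genes). Among the unchanged genes of these simulations the edgeR step made 15, 7, 7, 4 and 2 false calls in the same order, and DESeq2 made 32, 31, 23, 22 and 21. DESeq2 recovered 68, 68, 66, 67 and 27 of the genes changed 2-fold and 99, 97, 99, 98 and 82 of those changed 4-fold. The replicate cultures are biologically independent per the labels. Reads carry no molecular identifiers, so PCR copies are counted as reads, and the intervals and floors given here cover counting error only.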

Results

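Transcripts were measured in Phaeodactylum tricornutum, a unicellular marine diatom, to follow the role of nitrate reductase in intermediate metabolism, as the series title states. The wild type (WT, Pt1 8.6) and the transformant NR21 (NR), which the labels call a knock-down of nitrate reductase, were grown as 3 independent cultures each, and every culture was washed and divided over medium with 0.88 mM nitrate (plusN) and medium without a nitrogen source (minusN) for 48 h. The 12 libraries form 4 groups of 3, named below by their labels as WT_plusN, WT_minusN, NR_plusN and NR_minusN. Total counts in replicates 1, 2 and 3 were 5576887, 4638320 and 6075066 in WT_plusN and 2793955, 3905780 and 4355769 in WT_minusN. They were 3817500, 3758601 and 2489206 in NR_plusN and 3617165, 6344363 and 3852133 in NR_minusN. A floor of 3 counts in a library corresponds to 0.473 to 1.21 CPM (counts scaled to the library total) at these depths, and the most abundant gene took 1.29% to 3.23% of a library.

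Nitrate reductase reduces nitrate to nitrite and is the transcript targeted in NR21. Its gene model, Phatr2_54983, was at 86.7, 121 and 168 CPM in the libraries labelled WT_plusN (125 ± 40.7, SD, n = 3) and at 468, 429 and 346 CPM in the libraries labelled NR_plusN (414 ± 62.2, SD, n = 3). Without nitrogen it was at 1740, 3840 and 3950 CPM in the libraries labelled WT_minusN (3170 ± 1250, SD, n = 3) and at 1890, 1890 and 3020 CPM in the libraries labelled NR_minusN (2260 ± 652, SD, n = 3). The transcript rose without nitrogen by a log2 fold change of 4.66 (SE 0.39, edgeR adjusted p = 2.93e-06) in WT and of 2.45 (SE 0.36, adjusted p = 0.000257) in NR. With nitrate it was higher in all 3 libraries labelled NR_plusN than in all 3 labelled WT_plusN, by a log2 fold change of 1.73 (SE 0.35, adjusted p = 0.00808). This is the opposite of a lowered transcript, but the plan did not assume that the knock-down lowers the transcript. Without nitrogen the log2 difference of NR from WT was -0.49 (SE 0.34, adjusted p = 0.444). All 3 libraries labelled NR_minusN lay below WT_minusN replicates 2 and 3 (3840 and 3950 CPM) and above WT_minusN replicate 1 (1740 CPM). The difference between the strains' nitrogen responses was -2.21 (SE 0.48) and did not pass in the edgeR fit (adjusted p = 0.0638). It passed with DESeq2 (-2.19, adjusted p = 0.000988), without WT_minusN replicate 1 (-2.51, adjusted p = 0.0123) and without NR_minusN replicate 3 (-2.44, adjusted p = 0.028). The authors' deposited tables give log2 fold changes of 4.66, 2.48, 1.72 and -0.48 for this gene in the WT nitrogen, NR nitrogen, plusN strain and minusN strain comparisons, with adjusted p-values of 1.37e-09, 1.01e-05, 4.39e-11 and 1. The files do not state whether counting was strand-specific, so reads from an introduced construct could be part of these values. The targeted transcript was higher with nitrate and not called different without nitrogen, so it does not settle the label. Groups are called by their labels throughout, and the direction of every NR against WT comparison rests on those labels.

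**Figure D1:**
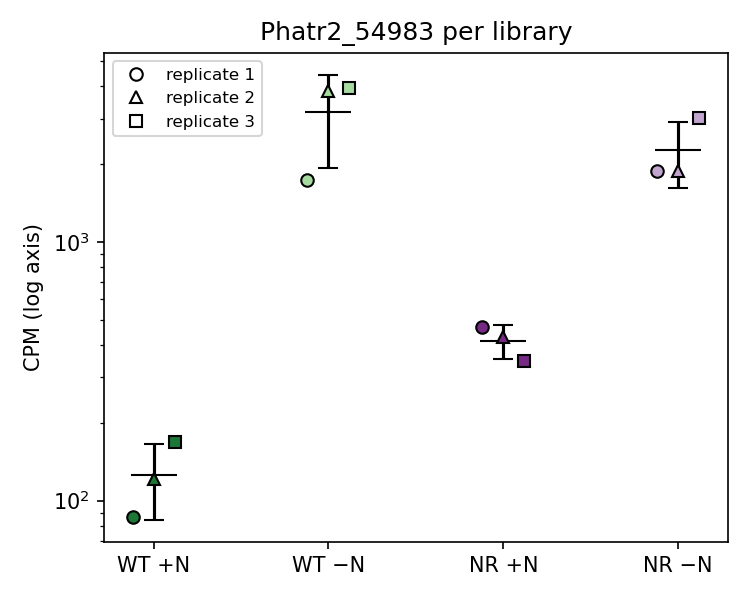
CPM of the targeted gene model Phatr2_54983 (log axis) in each of the 12 libraries by labelled group, with points for libraries, the horizontal bar for the mean and the vertical bar for 1 SD (n = 3). The group means are 125, 3170, 414 and 2260 CPM for WT_plusN, WT_minusN, NR_plusN and NR_minusN.

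Nitrogen separated the libraries most, with 74% of the variance of log2 CPM on the first principal component and 13.3% on the second. Libraries of one group correlated across genes at r = 0.99 to 0.993 in WT_plusN, 0.94 to 0.987 in WT_minusN, 0.97 to 0.986 in NR_plusN and 0.921 to 0.97 in NR_minusN. The library labelled WT_minusN replicate 1 stood apart from its group: it lay at 19.2 on the second component, where the other libraries labelled WT lay between -35.3 and -27.8. It correlated at 0.976 and 0.98 with the libraries labelled NR_minusN replicates 1 and 3, and at 0.94 and 0.947 with WT_minusN replicates 2 and 3. The library labelled NR_minusN replicate 2 also stood apart, at 8.1 on the first component, where the other minusN libraries lay between 59.7 and 73.6 and the plusN libraries between -64.7 and -54.6. Counts of changed genes and gene groups are therefore also given without both of these libraries, an alternative chosen after seeing the data.

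**Figure D2:**
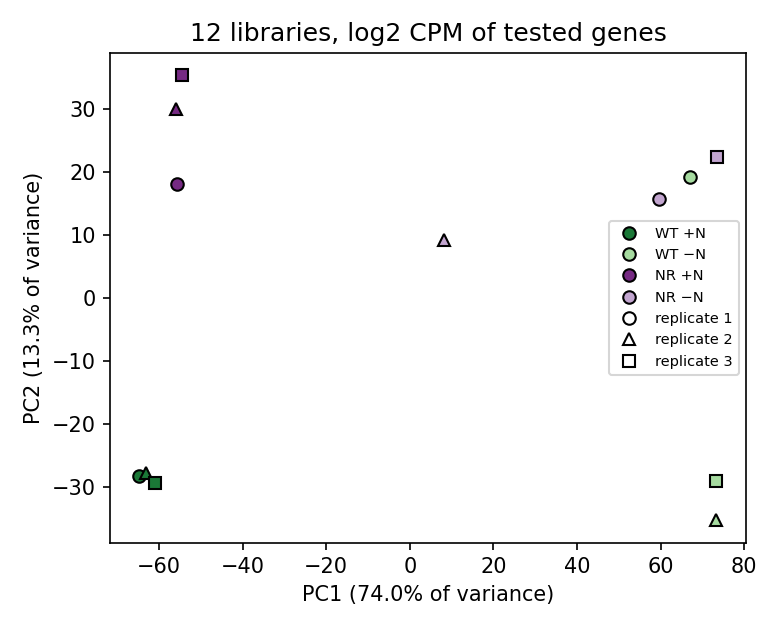
Principal components 1 (74% of variance) and 2 (13.3%) of log2 CPM over the 9717 tested genes, in component units, with 1 point per library coloured by labelled group and shaped by replicate. The library labelled WT_minusN replicate 1 sits at 19.2 on component 2 and NR_minusN replicate 2 at 8.1 on component 1, each away from the other libraries of its group.

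In the libraries labelled WT, loss of nitrogen was accompanied by a fall of transcripts for photosynthesis, pigments, carbon fixation, plastid fatty acid synthesis and chaperones. Of 25 light harvesting genes, which encode the fucoxanthin chlorophyll proteins of the antenna, 22 fell, 2 rose and 1 did not pass, with the same 22 and 2 when adjusted over the list alone. The light harvesting list had a median log2 fold change of -4.99 and a camera adjusted p = 4.39e-06, and adjusted p = 0.467 with an estimated correlation. Lhcf8 went from 1230 ± 77.8 CPM to 3.89 ± 0.824 CPM (SD, n = 3), a log2 fold change of -8.27 (SE 1.42, adjusted p = 0.000257), and Lhcf5 from 4620 ± 411 to 16 ± 5.54 CPM (-8.19, SE 1.40, adjusted p = 0.000252). Of 16 genes of tetrapyrrole and chlorophyll synthesis, 13 fell, 1 rose and 2 did not pass. The tetrapyrrole list had a median log2 fold change of -2.11 and a camera adjusted p = 0.000473, and adjusted p = 0.467 with an estimated correlation. In it hemE was at -4.72 (SE 0.74) and chlM at -3.51 (SE 0.69). The library labelled WT_minusN replicate 1, which stood apart, is part of these values, and without both libraries that stood apart hemE was at -6.47 and chlM at -5.24. Of 10 genes of the Calvin cycle and plastid carbon, 9 fell and 1 did not pass. The Calvin cycle list had a median log2 fold change of -2.82 and a camera adjusted p = 0.000509, and adjusted p = 0.467 with an estimated correlation. In that group Tpt3 went from 383 ± 10.2 to 4.16 ± 0.785 CPM (-6.50, SE 1.05) and GapC1 from 1590 ± 48.1 to 23.9 ± 7 CPM (-6.05, SE 1.07). Of 11 genes of fatty acid synthesis, 9 fell, 1 rose and 1 did not pass. The fatty acid synthesis list had a median log2 fold change of -3.20 and a camera adjusted p = 0.00767, and adjusted p = 0.467 with an estimated correlation. FABD, by its symbol the malonyl transferase of the pathway, was at -6.60 (SE 1.00) and FABI, the enoyl reductase, at -5.37 (SE 0.83). Of 6 photosystem and electron transport genes, 5 fell and 1 rose. The photosystem and electron transport list had a median log2 fold change of -2.85 and a camera adjusted p = 0.03, and adjusted p = 0.467 with an estimated correlation. PetJ, cytochrome c6, was at -5.83 (SE 0.93) and PsbO, of the oxygen-evolving complex, at -1.64 (SE 0.21). The shorter list fixed in advance for photosystems, 5 genes, held 3 that fell and 2 that rose, with the same counts adjusted over the list alone, and was not called (adjusted p = 0.358), and PSAT in it, which is read as an enzyme of serine synthesis, rose by 0.78 (SE 0.26, adjusted p = 0.0198), a call lost without WT_plusN replicate 1 or WT_minusN replicate 1.

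Genes of the replication fork, motor proteins and chaperones also fell in the libraries labelled WT without nitrogen. Of the 7 MCM and PCNA genes of the list fixed in advance, which serve the replication fork, 6 fell and 1 did not pass, also when adjusted over the list alone. The MCM and PCNA list had a median log2 fold change of -1.70 and a camera adjusted p = 0.0211, and adjusted p = 0.467 with an estimated correlation. MCM4 went from 86 ± 7.41 to 6.06 ± 1.91 CPM (-3.86, SE 0.48). The 26 genes of DNA replication and repair, with 15 lower and 5 higher, were not called as a list (adjusted p = 0.0753). Of 23 kinesins, myosins and dyneins, 15 fell, 1 rose and 7 did not pass. The motor protein list had a camera adjusted p = 0.0105, and adjusted p = 0.467 with an estimated correlation. DYNLRB, a dynein light chain, rose by 2.26 (SE 0.20). Of the 11 chaperone genes fixed in advance, 9 fell and 2 did not pass, with 9 falling when adjusted over the list alone. The fixed chaperone list had a median log2 fold change of -1.99 and a camera adjusted p = 0.00476, and adjusted p = 0.467 with an estimated correlation. HSP20A went from 10400 ± 1120 to 584 ± 189 CPM (-4.16, SE 0.68) and HSP20B from 12400 ± 1420 to 1020 ± 387 CPM (-3.60, SE 0.53). The wider list of 20 chaperones and heat shock factors had 14 that fell and 3 that rose. The wider chaperone list had a camera adjusted p = 0.0105, and adjusted p = 0.502 with an estimated correlation. Of 16 genes of carotenoid and plastid isoprenoid synthesis, 8 fell, 1 rose and 7 did not pass. The carotenoid list had a camera adjusted p = 0.0425, and adjusted p = 0.467 with an estimated correlation. ZEP1, read as zeaxanthin epoxidase, was at -3.01 (SE 0.33). The list was not called without the libraries labelled WT_minusN replicate 1 and NR_minusN replicate 2 (adjusted p = 0.0549).

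At the preset correlation, the other lists called for nitrogen in WT were also called without both of these libraries. Then 22 light harvesting genes fell and 2 rose (adjusted p = 2.04e-12), 13 tetrapyrrole genes fell and 1 rose (8.49e-06), and 10 Calvin cycle genes fell (8.49e-06). In fatty acid synthesis 9 fell and 1 rose (adjusted p = 0.00113), and in the photosystem and electron transport list 5 fell (0.00294). Of the MCM and PCNA genes 6 fell (adjusted p = 0.0088), of the motor protein genes 16 fell and 1 rose (0.0175), of the fixed chaperones 9 fell (0.000286), and of the wider chaperone list 14 fell and 3 rose (0.00115).

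In this comparison 6275 of 9717 genes changed by the edgeR test (64.6%), with 3157 higher and 3118 lower without nitrogen, and 6750 changed without the libraries labelled WT_minusN replicate 1 and NR_minusN replicate 2. At least a 2-fold change was seen for 1743 of the higher and 2047 of the lower genes. The genes that rose most were Phatr2_54101, from 0.937 ± 0.547 to 520 ± 190 CPM (log2 fold change 9.05, SE 0.53), and Phatr2_26029, from 56.3 ± 11.2 to 26300 ± 7630 CPM (8.87, SE 0.46). Phatr2_34932 fell most, with 1698 counts in the 3 WT_plusN libraries and 3 counts in the 3 WT_minusN libraries, a CPM ratio of 418 with a counting interval at 95% of 143 to 2030. Scaling by library size alone moved the median log2 fold change of all genes from 0.027 to 0.147, with 3508 genes higher and 2699 lower, and DESeq2 size factors gave 3110 higher and 3147 lower. No median of a called list changed sign under either other scaling.

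**Figure D3:**
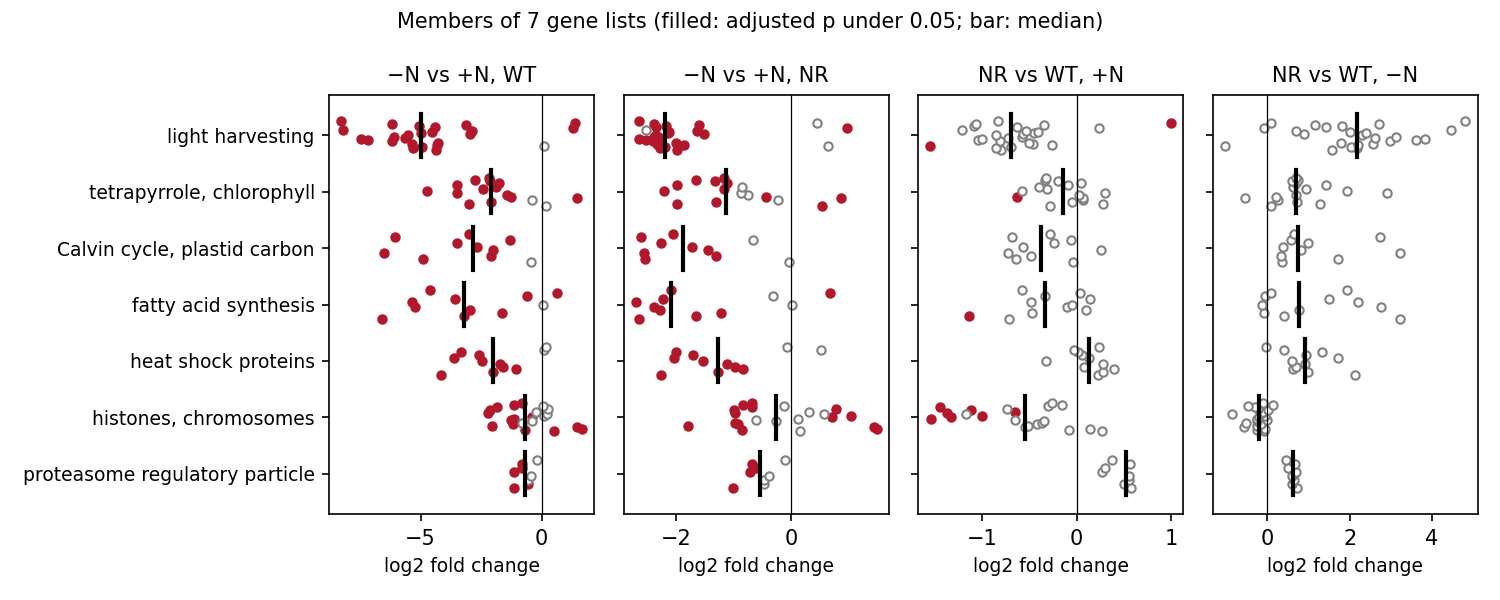
Log2 fold changes (x axis, with its own range in each panel) of the members of 7 gene lists in the 4 pairwise comparisons, with 1 point per gene, filled where the edgeR adjusted p was under 0.05, and a bar at the list's median. The median of the light harvesting genes lies at -4.99 in WT and -2.20 in NR without nitrogen, and at 2.17 for NR against WT without nitrogen, where no gene passed.

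In the libraries labelled NR, loss of nitrogen was accompanied by lower levels of many of these gene groups, and the library labelled NR_minusN replicate 2, which stood apart, is part of the SD values below. Of the 25 light harvesting genes 21 fell, 1 rose and 3 did not pass, with 22 falling and 2 rising when adjusted over the list alone. The light harvesting list had a median log2 fold change of -2.20 and a camera adjusted p = 8.39e-05, and adjusted p = 0.529 with an estimated correlation. Lhcr11 went from 875 ± 55.9 to 164 ± 215 CPM (SD, n = 3), a log2 fold change of -2.40 (SE 0.71, adjusted p = 0.0121). Without the libraries labelled WT_minusN replicate 1 and NR_minusN replicate 2, 22 fell and 1 rose, the median was -3.78 and Lhcr11 was at -4.43. Of 10 Calvin cycle and plastid carbon genes 8 fell and 2 did not pass. The Calvin cycle list had a median log2 fold change of -1.88 and a camera adjusted p = 0.00225, and adjusted p = 0.529 with an estimated correlation. In it Rpe was at -2.55 (SE 0.61) and TPI/GapC3, placed in the list by its symbol, at -2.26 (SE 0.44). The symbol of TPI/GapC3 gives no compartment, so it need not be a plastid or Calvin cycle enzyme. Of 16 tetrapyrrole genes 10 fell and 2 rose. The tetrapyrrole list had a median log2 fold change of -1.14 and a camera adjusted p = 0.011, and adjusted p = 0.529 with an estimated correlation. In this group hemE was at -2.21 (SE 0.62) and HY2 at -1.98 (SE 0.31). Of 11 fatty acid synthesis genes 8 fell and 1 rose. The fatty acid synthesis list had a median log2 fold change of -2.09 and a camera adjusted p = 0.011, and adjusted p = 0.529 with an estimated correlation. In this group FABI was at -2.70 (SE 0.68) and FABD at -2.65 (SE 0.71). Of 6 photosystem and electron transport genes 5 fell. The photosystem and electron transport list had a camera adjusted p = 0.0363, and adjusted p = 0.529 with an estimated correlation. OEE3, of the oxygen-evolving complex, was at -2.47 (SE 0.67). Of 16 carotenoid and plastid isoprenoid genes 9 fell. The carotenoid list had a camera adjusted p = 0.0231, and adjusted p = 0.529 with an estimated correlation. ZEP1 was at -1.66 (SE 0.31). Without both libraries that stood apart, Rpe was at -4.82, hemE at -3.35, FABI at -5.18, FABD at -6.43 and OEE3 at -4.24. At the preset correlation the lists were called there as well, with 9 Calvin cycle genes lower (adjusted p = 3.61e-05), 13 tetrapyrrole genes lower and 2 higher (0.000857), 8 fatty acid synthesis genes lower and 1 higher (0.000857), 5 photosystem and electron transport genes lower (0.00359) and 11 carotenoid genes lower (0.032).

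Replication, chaperone and motor protein genes were lower in the libraries labelled NR_minusN as well. Of the 7 MCM and PCNA genes 5 fell, also when adjusted over the list alone. The MCM and PCNA list had a camera adjusted p = 0.0231, and adjusted p = 0.529 with an estimated correlation. MCM4 went from 105 ± 9.36 to 21.1 ± 18.1 CPM (-2.27, SE 0.41). Of 26 genes of DNA replication and repair 12 fell and 14 did not pass. The DNA replication and repair list had a camera adjusted p = 0.0483, and adjusted p = 0.529 with an estimated correlation. POLA was at -1.69 (SE 0.25), and the list was not called without both libraries that stood apart (adjusted p = 0.142). Of the 11 chaperone genes fixed in advance 9 fell, also when adjusted over the list alone. The fixed chaperone list had a median log2 fold change of -1.27 and a camera adjusted p = 0.011, and adjusted p = 0.529 with an estimated correlation. HSP20A went from 12300 ± 1120 to 2560 ± 2950 CPM (-2.26, SE 0.62), and was at -3.84 without both libraries that stood apart. Without both, 5 MCM and PCNA genes fell (adjusted p = 0.0265), 9 fixed chaperones fell and 1 rose (0.000857), and in the wider chaperone list 14 fell and 4 rose (0.00897). In the wider chaperone list of 20, 14 fell and 3 rose. The wider chaperone list had a camera adjusted p = 0.0495, and adjusted p = 0.529 with an estimated correlation, and lost its call with the replicate number as a block. The rises include the heat shock factors HSF2 at 2.40 (SE 0.24) and HSF1 at 2.03 (SE 0.20). Of 23 motor proteins 10 fell and 2 rose. The motor protein list had a camera adjusted p = 0.0495, and adjusted p = 0.529 with an estimated correlation. The list was not called without both libraries that stood apart (adjusted p = 0.0643), nor with the replicate number as a block. The edgeR test called 5300 genes (54.5%), with 2553 higher and 2747 lower without nitrogen, and 6304 without both libraries that stood apart. Scaling by library size alone gave 2680 higher and 2446 lower. Phatr2_54101 rose most, from 0.835 ± 0.848 to 315 ± 102 CPM (8.40, SE 0.55), followed by Phatr2_26029, from 125 ± 23.6 to 18500 ± 6110 CPM (7.20, SE 0.43). In the fit of all 12 libraries the lowest fold changes under the naming rule were those of Phatr2_45565, from 17.3 ± 2.51 to 1.91 ± 1.97 CPM (-2.96, SE 0.42), and Phatr2_13706, from 169 ± 57.7 to 23.6 ± 29.8 CPM (-2.77, SE 0.64). This order depended on the libraries that stood apart: without both, Phatr2_45565 was at -4.41 and Phatr2_13706 at -4.72, above FABD at -6.43 and Lhcf8 at -6.98.

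Across the 9717 genes, the nitrogen responses of the libraries labelled WT and NR, which share no libraries, correlated at Pearson r = 0.88 and Spearman rho = 0.897 with a slope of 0.65 of NR on WT. Both libraries that stood apart are part of these responses, and NR_minusN replicate 2 lay toward the plusN libraries. The slope is therefore not a measure of a weaker response in NR, and none is given without these libraries. Genes are not independent replicates, and no p is given. A rise in both strains was called for 2238 genes, where independent lists would share 829, and a fall in both for 2371, where independent lists would share 881, while 17 genes were called in opposite directions.

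With nitrate, the libraries labelled NR_plusN differed from those labelled WT_plusN in histone genes and in single genes of pyruvate, C4 acid and amino acid metabolism, with the directions resting on labels that the targeted transcript does not settle. Of 21 genes for histones and chromosome structure, 7 were lower, 0 higher and 14 did not pass. The histone list had a median log2 fold change of -0.55 and a camera adjusted p = 4.46e-05, and adjusted p = 0.555 with an estimated correlation. H2B-1a was at 104 ± 5.51 CPM in the libraries labelled WT_plusN and 38 ± 4.62 CPM in those labelled NR_plusN (SD, n = 3), a log2 fold change of -1.45 (SE 0.23, edgeR adjusted p = 0.00291), and H2A-3b at 94.7 ± 6.06 and 37.7 ± 2.26 CPM (-1.33, SE 0.17, adjusted p = 0.000768). TRPB, by its symbol the beta chain of tryptophan synthase, was at 84.6 ± 6.14 and 5.83 ± 1.92 CPM (-3.88, SE 0.24, adjusted p = 6.95e-06). PYC1, read as pyruvate carboxylase, was at 409 ± 20.6 and 135 ± 12.3 CPM (-1.60, SE 0.19, adjusted p = 0.00073), MS at 496 ± 53.9 and 212 ± 20.9 CPM (-1.22, SE 0.18, adjusted p = 0.00165), and PEPCK1, read as phosphoenolpyruvate carboxykinase, at 741 ± 51.3 and 365 ± 21 CPM (-1.02, SE 0.18, adjusted p = 0.00407). Fum went the other way, from 72.1 ± 4.64 to 180 ± 38.2 CPM (1.32, SE 0.26, adjusted p = 0.00717). The list of 22 pyruvate, C4 acid and tricarboxylic acid cycle genes, with 5 lower and 1 higher, was not called (adjusted p = 0.143), nor was that of 15 other amino acid synthesis genes, with 2 lower and 1 higher (adjusted p = 0.863).

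Lists of proteasome, motor protein, transporter and light harvesting genes were examined in the same comparison. None of 8 regulatory subunits of the proteasome passed singly, also when adjusted over the list alone, while the list stood higher in the libraries labelled NR_plusN (median 0.53, camera adjusted p = 0.0401, and adjusted p = 0.892 with an estimated correlation). With the replicate number as a block the proteasome list was not called. RPN12 was at 0.37 (SE 0.13, adjusted p = 0.0832), and without both libraries that stood apart 6 of the 8 passed as higher. Of 23 motor protein genes 2 were lower. The motor protein list had a camera adjusted p = 0.0401, and adjusted p = 0.844 with an estimated correlation, and lost its call with the replicate number as a block. Of 4 silicic acid and bicarbonate transporter genes 2 were lower (adjusted p = 0.0401, and adjusted p = 0.555 with an estimated correlation). Without both libraries that stood apart, 12 motor protein genes were lower and 2 higher (adjusted p = 0.0164), 4 transporter genes were lower (0.0153), and 11 histone genes were lower (2.4e-05). Of the light harvesting genes 1 was lower, 1 higher and 23 did not pass, with the same counts adjusted over the list alone, and the list was not called (median -0.70, adjusted p = 0.143). Without both libraries that stood apart, which are minusN libraries and enter through the shared estimate of spread, the scaling and the filter, 20 light harvesting genes were lower and 1 higher with the same median (adjusted p = 6.59e-09, and adjusted p = 0.374 with an estimated correlation).

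For the strains with nitrate the edgeR test called 1435 genes (14.8%), 677 higher and 758 lower in the libraries labelled NR_plusN, and 3263 without both libraries that stood apart. The count was 572, 625 and 609 without WT_plusN replicates 1, 2 and 3, 441 and 568 without NR_plusN replicates 2 and 3, and 2215 without NR_minusN replicate 2. The fit to the 6 compared libraries alone called 3787. The balance of directions depended on the scaling and the libraries, with 730 higher and 641 lower by library size alone, and 217 higher and 392 lower without WT_plusN replicate 3. Phatr2_36007 and Phatr2_33638 were highest in the libraries labelled NR_plusN relative to WT_plusN, with 106 counts against 1 (CPM ratio 168, counting interval 29.5 to 6700) and 88 counts against 1 (ratio 140, 24.4 to 5570). Phatr2_bd_417 had no count in the 3 libraries labelled NR_plusN and 116 counts in those labelled WT_plusN (edgeR adjusted p = 0.0244). Against a floor of 3 counts over the group this is 24.4-fold lower, and the counting interval reaches down to 19.5-fold. Phatr2_bd_417 was no longer called without WT_plusN replicate 1 or 2 or without NR_plusN replicate 1, 2 or 3, where its adjusted p reached 0.0846. Phatr2_41316 was at 527 ± 371 CPM in WT_plusN and 14.8 ± 1.67 CPM in NR_plusN (-5.15, SE 0.93, adjusted p = 0.005).

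The strain difference with nitrate was set against the nitrogen response of WT, which shares the WT_plusN libraries. Across 9717 genes the fold changes correlated at r = 0.272 (rho = 0.245) with a covariance of 0.266. In 20 simulations all 12 libraries were drawn anew, gene by gene, from the mean WT_plusN profile. They gave r = 0.448 to 0.485 and a mean covariance of 0.045, a covariance difference of 0.221. The simulations hold no strain effect, no nitrogen effect and no correlation between genes, so they show only what shared control libraries give. With WT_plusN libraries divided between the comparisons, the 6 choices gave r = 0.227 to 0.279 and covariances of 0.233 to 0.282. They had 1 to 87 genes higher in both (1 to 52 for independent lists) and 23 to 160 lower in both (11 to 87). With WT_plusN replicate 3 alone for the strain contrast, 1 gene was higher in both, against 1 for independent lists. In the undivided fit, genes called higher in both numbered 315 (220 for independent lists), lower in both 390 (243) and opposite 194 (464). Leaving out 1 library moved them to 89 to 451, 144 to 649 and 44 to 425, lowest without NR_plusN replicate 2 and highest without NR_minusN replicate 2, or WT_minusN replicate 1 for opposite calls. Without WT_minusN replicate 1 the correlation was 0.163, with 346 higher in both (298 for independent lists), 472 lower in both (345) and 425 opposite (643). Without both libraries that stood apart, 574 were higher in both (552 for independent lists), 857 lower in both (577) and 893 opposite (1129), so genes higher in both were then close to the number for independent lists.

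Without nitrogen, no gene passed between the strains in the edgeR test (smallest adjusted p = 0.126), with 1948 genes at an unadjusted p under 0.05, while DESeq2 called 244 (151 higher and 93 lower in the libraries labelled NR_minusN) and the authors' deposited table had no gene at an adjusted p under 0.05 and 405 at an unadjusted p under 0.05. In simulated data DESeq2 made 22 false calls in this comparison and edgeR 4. There DESeq2 recovered 67 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, against 53 and 94 with edgeR. As groups, transcripts for light harvesting, tetrapyrroles, chaperones and the proteasome stood higher in the libraries labelled NR_minusN. Of 25 light harvesting genes 0 passed over all genes, and 21 were higher and 1 lower when adjusted over the list alone (median log2 difference 2.17, camera adjusted p = 3.86e-07, and adjusted p = 0.466 with an estimated correlation). Lhcf4 was at 10.9 ± 5.81 CPM in the libraries labelled WT_minusN and 128 ± 183 CPM in those labelled NR_minusN (SD, n = 3), with a log2 difference of 3.60 (SE 0.88, edgeR adjusted p = 0.144). Without the libraries labelled WT_minusN replicate 1 and NR_minusN replicate 2, which stood apart, the median of the list was 0.71, with 12 genes higher and 1 lower. For the other groups the counts are those adjusted over the list alone, with 0 passing over all genes. Of 16 tetrapyrrole genes 8 were higher (median 0.70, adjusted p = 2.36e-06, and adjusted p = 0.466 with an estimated correlation), of 8 proteasome subunits all 8 (median 0.62, adjusted p = 1.09e-05, and adjusted p = 0.466 with an estimated correlation), and of 11 chaperone genes fixed in advance 8 (median 0.91, adjusted p = 0.000212, and adjusted p = 0.466 with an estimated correlation). The wider chaperone list (adjusted p = 0.000246), the photosystem and electron transport list (0.0102) and the Calvin cycle list (0.0105) were also higher, and those of cell cycle (0.0071) and histone genes (0.0206) lower, each with adjusted p = 0.466 with an estimated correlation. The Calvin cycle list was not called without both libraries that stood apart (median -0.08, adjusted p = 0.978), and 12 tetrapyrrole, 7 proteasome and 6 fixed chaperone genes were then higher over all genes. The count of called genes was 2141 without both, 1489 without WT_minusN replicate 1 alone and 197 without NR_minusN replicate 3.

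Whether the nitrogen response itself differed between the labelled strains was tested by the interaction, which 39 genes passed in the edgeR test, 31 with a more positive and 8 with a more negative response in NR. TRPB fell in WT without nitrogen, from 84.6 ± 6.14 to 6.57 ± 1.31 CPM (SD, n = 3), and was at 5.83 ± 1.92 and 6.68 ± 1.26 CPM in NR, a difference of responses of 3.89 on the log2 scale (SE 0.36, adjusted p = 0.000703). PYC1 went from 409 ± 20.6 to 187 ± 27.2 CPM in WT and from 135 ± 12.3 to 181 ± 45.1 CPM in NR (1.55, SE 0.27, adjusted p = 0.0274), and MS from 496 ± 53.9 to 156 ± 16.4 CPM in WT and from 212 ± 20.9 to 167 ± 29.3 CPM in NR (1.32, SE 0.25, adjusted p = 0.0362). PYC1 was no longer called without any one of WT_plusN replicates 1, 2 and 3, WT_minusN replicate 3 and NR_plusN replicates 1, 2 and 3, with an adjusted p of up to 0.118 over the alternatives. MS was no longer called without any one of these libraries or without WT_minusN replicate 2, with an adjusted p of up to 0.125. TRPB and Phatr2_44347 were called under every alternative, each with an adjusted p of at most 0.0168. Among the genes that passed, Phatr2_44347 had the largest positive difference (4.50, SE 0.48, adjusted p = 0.00208), at 766 ± 248 and 8.9 ± 0.606 CPM in WT and 41.5 ± 11.8 and 10.7 ± 5.28 CPM in NR with and without nitrogen. As a group, the 25 light harvesting genes had a less negative response in NR, with 0 passing over all genes and 22 more positive and 1 more negative when adjusted over the list alone (median 2.85, camera adjusted p = 4.54e-08, and adjusted p = 0.572 with an estimated correlation). Lhcf4 had a difference of 4.64 (SE 1.16, adjusted p = 0.0967), and without both libraries that stood apart 17 light harvesting genes passed over all genes (median 1.54, and adjusted p = 0.0557 with an estimated correlation). The tetrapyrrole list was also called (median 0.92, adjusted p = 3.06e-06, and adjusted p = 0.572 with an estimated correlation), with 12 genes passing without both.

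Of the remaining lists called for the interaction, those of the Calvin cycle (adjusted p = 0.00745), histones (0.011) and fatty acid synthesis (0.013) were not called without both libraries that stood apart (0.0949, 0.431 and 0.298). With an estimated correlation their adjusted p-values were adjusted p = 0.572, 0.572 and 0.58. The wider chaperone list (adjusted p = 0.00745), acyl-CoA synthetases and thiolases (0.0109) and photorespiration (0.0486) had adjusted p = 0.572, 0.52 and 0.52 with an estimated correlation. These 3 lists were also called without both libraries (adjusted p = 0.000438, 0.00724 and 0.00724). The fit treats all libraries as independent, although the cultures were divided over the media, because the labels do not say which plusN and minusN libraries come from the same culture. With the replicate number as a block 23 genes passed the interaction, and 6 passed with the block within strain. DESeq2 called 298 genes for the interaction, and in simulated data it made 21 false calls there, against 2 with edgeR. In the same simulated data DESeq2 recovered 27 of 100 genes changed 2-fold and 82 of 100 changed 4-fold, against 11 and 72 with edgeR. The count of 39 genes rose to 744 without both libraries that stood apart. Each library left out moved it by over 1.5 times. It was 11, 13 and 14 without WT_plusN replicates 1, 2 and 3, 192, 19 and 15 without WT_minusN replicates 1, 2 and 3, 24, 10 and 14 without NR_plusN replicates 1, 2 and 3, and 137, 90 and 377 without NR_minusN replicates 1, 2 and 3.

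The authors' deposited tables list 5620 genes at an adjusted p under 0.05 for nitrogen in WT, 2879 for nitrogen in NR, 2589 for the strains with nitrate and 0 for the strains without nitrogen. The edgeR fit also called 5527, 2860 and 1376 of the genes in the first 3 of the authors' deposited tables, all in the same direction.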

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

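The split test was planned before the results were seen. The interaction was passed by 39 genes in the edgeR fit, and 12 of 100 splits of the libraries reached this count, with the highest other at 2262. Of the 11 other splits that kept the plusN libraries in their groups 10 reached it, and of the 88 that mixed them 1 did (49 genes), a breakdown made after the result was seen. The splits of the first kind carry the strain difference with nitrate, so they are not free of an effect, and the share of 12 in 100 does not decide whether chance gave the 39. That splits of this kind called several times the real count points to a structure of the samples, which includes that strain difference. Among the genes that passed, the nitrogen response of Phatr2_44347 in NR against WT differed by 4.50 on the log2 scale, and TRPB by 3.89, and both were called under every alternative. PYC1 differed by 1.55, MS by 1.32, Phatr2_49286 by 4.11, Phatr2_34132 by -3.24 and Phatr2_42585 by -2.11, and each of these 5 lost its call without WT_plusN replicate 1, without WT_plusN replicate 3 or without NR_plusN replicate 2.

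The levels of TRPB and PYC1 were apart between the strains with nitrate and close to each other without nitrogen. TRPB was at 84.6 ± 6.14 CPM in WT_plusN and 5.83 ± 1.92 CPM in NR_plusN (SD, n = 3), and at 6.57 ± 1.31 and 6.68 ± 1.26 CPM in WT_minusN and NR_minusN. PYC1 was at 409 ± 20.6, 135 ± 12.3, 187 ± 27.2 and 181 ± 45.1 CPM in WT_plusN, NR_plusN, WT_minusN and NR_minusN.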

How the results depend on the processing

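Conclusions on the strains depended on the library set, the test and the gene-list method, and the cause was not tested. With at least a 2-fold change required, 3790 genes were called for nitrogen in WT, 2830 for nitrogen in NR and 626 for the strains with nitrate. The strain count with nitrate ranged from 441 to 2215 over single libraries left out, and was 3263 without WT_minusN replicate 1 and NR_minusN replicate 2 and 3787 with only the compared groups. The strain count without nitrogen ranged from 0 to 1489, and was 2141 without both libraries and 244 with DESeq2. The interaction count ranged from 10 to 377, and was 744 without both and 298 with DESeq2. With the replicate number as a block it was 23, and 6 with the block within strain. Each culture was divided over the media, but the labels do not say that equal replicate numbers mark the parts of 1 culture. Deviations from the group means in the 6 same-number pairs of a strain correlated at -0.07 to 0.13, with 2 over 0.1. Each library was also compared with the 3 libraries of its strain at the other nitrogen level. Of 12 libraries 8 correlated best with their own number, so pairing by replicate number stays open. The targeted gene's interaction ranged from -2.51 to -1.99 over single libraries left out, including -2.44 without NR_minusN replicate 3, and was -2.39 without both and -2.19 with DESeq2. Over the 427 named gene results, 9130 alternative values were 8526 times the same, 376 times weaker, 228 times stronger and 0 times reversed, and this run was extended from the genes of called lists to all named genes after the first text was written. Weaker means that a call was lost and stronger that one was gained. A change of sign counts as reversed only if the gene was called in at least 1 of the 2 fits, and otherwise as the same.

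Lists called numbered 10, 11, 4, 9 and 8 in the 5 comparisons, in the order nitrogen in WT, nitrogen in NR, strains with nitrate, strains without nitrogen and interaction. With an estimated correlation 0 were called in all 5. With fry 25, 25, 3, 0 and 1 were called, and with the replicate block 10, 9, 2, 9 and 8. The block ended the calls of the wider chaperone list (adjusted p = 0.0575) and the motor protein list (0.0548) for nitrogen in NR, and of the proteasome (0.0588) and motor protein lists (0.0559) for the strains with nitrate. Adjusted over all lists and comparisons together, the carotenoid list for nitrogen in WT was not called (camera adjusted p = 0.0544). For nitrogen in NR, the DNA replication and repair (0.0544), wider chaperone (0.0614) and motor protein lists (0.0618) were then not called. The correlation of the nitrogen responses ranged from 0.856 to 0.898 over single libraries left out, and was 0.894 without both and 0.898 for genes of at least 5 CPM. The correlation of the strain difference with the WT nitrogen response ranged from 0.163 to 0.321, and was 0.163 without both and 0.227 with WT_plusN replicate 3 alone for the strain contrast.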

Other observations

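Several gene groups without a called list contained single genes that changed with nitrogen. Of 22 pyruvate, C4 acid and tricarboxylic acid cycle genes, 9 rose and 5 fell in the libraries labelled WT (camera adjusted p = 0.449) and 11 rose and 4 fell in those labelled NR (adjusted p = 0.0951). FUM1 rose from 113 ± 5.94 to 406 ± 149 CPM in WT (SD, n = 3, log2 fold change 1.85, SE 0.25), and PEPCK1 rose from 365 ± 21 to 932 ± 12.2 CPM in NR (1.35, SE 0.18). Of 10 genes of glutamate metabolism, 3 rose and 1 fell in WT (adjusted p = 0.624), with GltD, read as a subunit of glutamate synthase, at 219 ± 7.62 and 602 ± 10.3 CPM (1.46, SE 0.17), and 3 rose and 0 fell in NR (adjusted p = 0.322). CPS-II, carbamoyl phosphate synthetase by its symbol, rose by 2.42 (SE 0.40) in WT and by 2.44 in NR. Of 8 iron genes, 5 rose and 2 fell in WT (adjusted p = 0.4), with ISIP1 at 2.93 and ISIP2A at -2.93. Of 31 ubiquitin genes, 18 rose and 7 fell in WT (adjusted p = 0.0753).

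Of the 6 lists fixed in advance, those of photosystems, of ribosomal proteins and of C3 and C4 acid carboxylation were called by camera in no comparison. Fry called that of photosystems for nitrogen in WT (fry adjusted p = 0.00113) and in NR (0.0125). Of 4 ribosomal protein genes 0 passed in WT (adjusted p = 0.749) and 0 in NR (adjusted p = 0.814), also when adjusted over the list alone. Of the 3 carboxylation genes, 1 rose and 1 fell in WT (adjusted p = 0.624), also when adjusted over the list alone, with PEPCase_1 at -2.17 (SE 0.38) and PEPCK1 at 0.48 (SE 0.17, adjusted p = 0.0261). The call of PEPCK1 was lost without WT_plusN replicate 1 or 3 or WT_minusN replicate 2.

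The tests of the mislabelled sample, the WT culture in an NR-like state, the mixed sample, partial stress, construct reads and the partly depleted state were chosen only after the result was seen, and those of library depth and RNA carry-over were written before it. The bounds of the NR-like state and partly depleted tests were reworded after their results were seen, which moved both to undecided. The library labelled WT_minusN replicate 1 lay with the libraries labelled NR_minusN. Over 16 genes that mark the strains by at least 3-fold, a bound set before running, its position from WT (0) to NR (1) was 0.89, and at 2-fold, added after seeing that 3-fold gave 16 genes, it was 0.91. At 3-fold WT_minusN replicates 2 and 3 lay at 0.02 and 0 and NR_minusN replicates 1 and 3 at 0.91 and 0.84. The marking genes were chosen anew for each library from the others, so each position rests on its own set of genes. Thinned to the depth of WT_minusN replicate 1, WT_minusN replicates 2 and 3 lay at 0.03 at most, which argues only against counting noise at that depth. Thinning keeps the expected profile, so other effects of depth were not tested. A mislabelled sample fits the pooled position, while the 6 WT-marking genes alone gave 0.73 and the NR-marking genes 1.07, and 68.4% of 19 WT-marking genes at 2-fold lay above the NR libraries other than NR_minusN replicate 2, against 48.3% of 29 and 20% of 20 for NR_minusN replicates 1 and 3. A WT culture in an NR-like state cannot be told apart from it: 0.0% of the 16 genes, and 0.0% of 51 at 2-fold, lay within the range of the other libraries labelled WT (50% and 43.3% at 2-fold for WT_minusN replicates 2 and 3, each on its own set of genes), but the genes were chosen by expression, which such a state could move.

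The library labelled NR_minusN replicate 2 lay between the plusN and minusN libraries. A mixture of RNA from a plusN and a minusN culture passed its test: with WT_minusN as the minusN source, the fractions from falling and rising genes, 0.46 and 0.51, differed by 0.05. With this source the difference was 0.02 and 0.07 for WT_minusN replicates 2 and 3, at fractions of at most 0.08. It was 0.3 and 0.25 for NR_minusN replicates 1 and 3. With NR_minusN as the minusN source, the difference was 0.04 for NR_minusN replicate 2, and 0.35 and 0.08 for NR_minusN replicates 1 and 3. For WT_minusN replicates 2 and 3 it was then 0.11 and 0.0. No partly stressed culture was simulated, so a small difference does not by itself mark a mixture. Thinned to the lowest depth of the series, NR_minusN replicate 2, which had the most counts (6344363), kept a plusN share of 0.46. Thinning keeps the expected profile, so the test does not decide on depth for this library. On the 6 genes that mark WT alone, which are low in the other NR libraries, its position was 0.34 (0.44 on 19 genes at 2-fold), against 0.98 on 9 genes and 0.92 on 6 for NR_minusN replicates 1 and 3, which argues against partial nitrogen stress of an NR culture. Over all marking genes its position was 0.6, and on those that mark NR 1.23. A fit of its profile by those of the groups gave shares of 0.46 NR_plusN, 0.34 WT_minusN (0.29 to 0.4 over single reference libraries) and 0.2 NR_minusN, but these shares leave the origin of a minusN part open, because NR_minusN replicates 1 and 3 also took WT_minusN shares of 0.23 and 0.27 and NR_plusN replicate 1 a WT_plusN share of 0.27. At 2-fold, 100% of 19 WT-marking genes lay above all other libraries labelled NR. By the same measure, with replicate 2 left out, NR_minusN replicates 1 and 3 had 48.3% of 29 and 20% of 20. This goes with some WT RNA in NR_minusN replicate 2, although the genes were chosen by expression.

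The targeted transcript was higher in the libraries labelled NR_plusN than in WT_plusN. Over 13 strongly induced genes, the median share of minusN RNA was 0.09 of the share that the targeted transcript would need, which argues against carry-over. Construct reads were tested by the excess in NR against WT over all 12 libraries, at -910 CPM without nitrogen and 289 CPM with nitrate. Without nitrogen, the libraries labelled NR_minusN (at most 3020 CPM) lay below WT_minusN replicates 2 and 3 (3840 and 3950 CPM). WT_minusN replicate 1, which stood apart, was lower, at 1740 CPM, and left the test undecided. Without that library the rule of this test would have counted against construct reads, but the rule cannot decide on them. It assumes that a construct adds as many reads without nitrogen as with nitrate, which was not tested. The excess of 289 CPM is also small beside the range within NR_minusN, 1890 to 3020 CPM. Construct reads cannot be told apart from a higher native transcript, since gene-level counts hold no sequence. A partly depleted state of the NR_plusN cultures also cannot be told apart, because the covariance with the WT nitrogen response was 0.164 without both libraries that stood apart, above the maximum of 0.027 in simulations of that fit and of 0.048 in those of the fit of all 12 libraries, while strongly induced genes gave a share of only 0.007. The simulations hold no strain or nitrogen effect, so a covariance above their maximum does not by itself point to a depleted state.

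The splits of libraries were planned before the results. For nitrogen in WT 1 of 10 splits reached the real count of 6275 (highest other 0), for nitrogen in NR 1 of 10 reached 5300 (highest other 0), and for the strains with nitrate 1 of 10 reached 1435 (highest other 0). For the strains without nitrogen 10 of 10 reached the real count of 0, and the highest other was 1093. With 10 splits, these are too few for a share under 0.05. That 1093 genes were called when WT_minusN replicate 1 was placed with NR_minusN replicates 1 and 3 points to a structure of the samples other than the labels.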
